A study of Mus musculus with 6 samples.

How the data were processed

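The series holds 6 Affymetrix arrays of RNA from sorted splenic dendritic cells of wild-type mice, 2 for each of CD24+ cDC1, CD24+CD172a+ cDC2 and CD24-CD172a+ cDC2. Per the labels' protocols, total RNA was extracted on columns and biotinylated cDNA was made with the Affymetrix WT Pico reagent kit. Per the submitters' processing notes, the arrays were processed in Affymetrix Expression Console with RMA, which corrects background, quantile-normalises the arrays and summarises each probe set by median polish; neither versions nor a genome build are stated. The deposited values are RMA intensities on a linear scale, as their range shows (array medians from 29.5 to 30.6 and maxima from 11459 to 12095), so their log2 was taken before every test. Scanner files and detection calls were not used here, so background, scan dates and the signal over background of single probe sets were not examined. Samples were grouped by the populations in the labels, and replicate numbers came from the sample titles.

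Of 28853 probe sets, the 21789 with a single gene symbol were used. A further 1621 with several symbols and 5443 without one were left out of the tests of genes. Gene IDs of 21698 of those used were found in a reference gene table of assembly GRCm38.p6, which was used for names only and changed 0 symbols. Where a gene had several probe sets (999 genes), the one with the highest mean over all 6 arrays was kept, which left 19938 genes with no filter on dim ones. Among called genes with several probe sets, a dimmer probe set had the other sign in 2 of 15, 19 of 187 and 19 of 215 in the 3 comparisons, and in 0 of them was that probe set called.

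The populations were compared pairwise with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend), with all 6 arrays in 1 fit. This gave 3 residual degrees of freedom, 7.31 prior degrees of freedom and a prior standard deviation of 0.145. Each comparison was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Overlaps of calls between comparisons that share arrays were set beside the overlap of independent lists and beside 100 simulations of unchanged groups sharing those arrays. The position of CD24+CD172a+ cDC2 was the median over 200 genes of its distance from CD24-CD172a+ cDC2, divided by the distance of cDC1, with genes chosen on the replicate 1 arrays of those groups and measured on the replicate 2 arrays, and the reverse.

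Before the data were examined, 27 gene lists were fixed, with 481 of 525 genes measured. They cover cDC1 and cDC2 identity, ESAM-high and ESAM-low cDC2, dendritic cell transcription factors, MHC class I and II presentation, innate sensors, C-type lectins, chemokines, cytokines, maturation, interferon-stimulated genes, the Notch pathway, the cell cycle, cholesterol synthesis, immediate-early and heat shock genes, integrins, and granule and cytotoxic genes. The other lists hold markers of plasmacytoid dendritic cells, monocytes and macrophages, B, T and NK cells, neutrophils, erythroid cells, and migratory and transitional dendritic cells. Lists were tested against all other genes by camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation was an alternative. Fry was also run, which asks another question, whether a list's genes move one way on balance, and compares them with no other genes.

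The rule for named genes was fixed at the same time. It takes the sort markers and 8 regulators whatever their values. It adds the 8 largest and 8 smallest fold changes among called genes whose arrays do not overlap and whose higher group lies above the median gene, without predicted genes, clone names or antigen receptor segments. Each list described gives up to 4 called members, or else the 2 with the smallest p, and the genes higher or lower than in both other populations give 6 of each direction.

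The alternatives, fixed at the same time, were filters on dim genes, all probe sets, the mean of a gene's probe sets, quantile normalisation again, median centring, cyclic loess, an intensity trend with robust variance, array weights, only the 2 groups compared, treat against a 1.5-fold change, the replicate number as a block, and leaving out each array in turn. For the position, the number and choice of genes were varied. The tests were first run on simulated data for CD24+CD172a+ against CD24-CD172a+ cDC2, with 200 of 19938 genes changed in each of 10 simulations. They recovered 7.01% of genes changed by a log2 of 0.5, 86.3% of those changed by 1 and 100% of those changed by 2, with 4.45% of calls false. A list shifted by 0.5 was called in 10 of 10 simulations, and in 9 with an estimated correlation. Noise was drawn independently for each gene, so these simulations do not show how either setting fares with correlated genes. A simulated position of 0.25 was recovered as 0.254. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.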

Results

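Gene expression was measured on 6 Affymetrix arrays, each hybridised with RNA from 1 of 3 dendritic cell populations sorted from the spleens of wild-type mice. Conventional dendritic cells fall into type 1 (cDC1), which present exogenous antigen to CD8 T cells, and type 2 (cDC2), which carry CD172a on their surface. The populations were CD24+ cDC1, CD24+CD172a+ cDC2 and CD24-CD172a+ cDC2, with 2 arrays each. The median intensity per array ran from 29.5 to 30.6 and the highest from 11459 to 12095. Replicate arrays correlated at 0.993 in cDC1, 0.993 in CD24+CD172a+ cDC2 and 0.992 in CD24-CD172a+ cDC2, across genes, which are not independent replicates. Arrays of the 2 cDC2 populations correlated with each other at 0.988 to 0.989, and with cDC1 arrays at 0.959 to 0.963. The first principal component, with 69.6% of the variance, set cDC1 apart from both cDC2 populations, and the second, with 12.9%, set the cDC2 populations apart. The labels do not say whether the 2 arrays of a group came from separate animals. The p-values of limma thus rest on the spread between these arrays, together with a prior drawn from all genes, and the number of arrays limits the precision. Those of camera with the preset correlation set a list's genes against all other genes, so they do not measure the spread between arrays. In all that follows, levels are log2 intensities with their SD (n = 2 arrays), fold changes are given on the log2 scale with their standard error, and a gene is called when its adjusted p from limma is under 0.05. For each comparison, 2 of the 6 fits with 1 array left out drop an array of the population not compared. A lone array adds no spread, so these 2 give the same result and count as 1 check. Only the other fits drop a compared array. Tallies out of 6 fits below still count the 2 separately. Between the cDC2 populations, every called named gene with a tally of 2 or more kept its call in both. A tally of 2 there thus holds no fit that drops a compared array, and a tally of 3 holds 1.

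**Figure D1:**
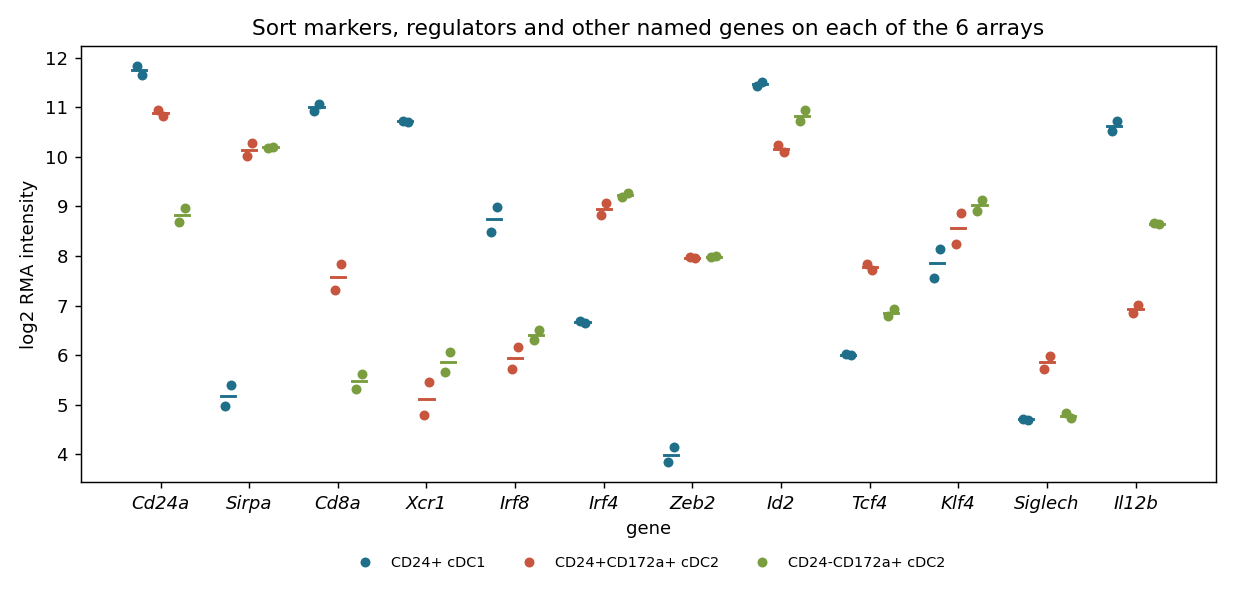
Log2 RMA intensity (y axis) of 12 genes (x axis) on each of the 6 arrays, coloured by population; dots are arrays and lines are group means. Cd24a had a mean of 11.74 in cDC1, 10.88 in CD24+CD172a+ cDC2 and 8.83 in CD24-CD172a+ cDC2, while Sirpa was at 10.14 in CD24+CD172a+ and 10.19 in CD24-CD172a+ cDC2 against 5.18 in cDC1.

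The first comparison asks how cDC2 that carry CD24 differ from those that lack it. Cd24a, which encodes the sort marker CD24, was 4.14-fold higher in CD24+CD172a+ cDC2 (10.88 ± 0.09 against 8.83 ± 0.20, SD, n = 2). Cd8a, the CD8 alpha chain carried by splenic cDC1, was 4.31-fold higher, at 7.58 ± 0.37 against 5.47 ± 0.22. Il12b, the p40 subunit of interleukin 12, was 3.29-fold lower, at 6.93 ± 0.12 against 8.65 ± 0.02. Of 27 gene lists, camera with the preset correlation called 2 higher, the cell cycle and plasmacytoid dendritic cell markers, and 10 lower, monocyte and macrophage markers and interferon-stimulated genes among them. With an estimated correlation it called 0 (6 had an unadjusted p under 0.05), and fry, which compares a list with no other genes, called 6.

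Sirpa, which encodes CD172a, differed by -0.05 ± 0.16 (adjusted p = 0.927) between the cDC2 populations. Among the regulators, Tcf4, an E protein needed for plasmacytoid dendritic cells, rose by 0.91 ± 0.13 (adjusted p = 0.00973), a call kept in 3 of 6 fits with 1 array left out. Id2, an inhibitor of E proteins, fell by 0.66 ± 0.14 (adjusted p = 0.0462), a call that no fit with 1 array left out kept. Irf8 and Batf3, which cDC1 require, differed by -0.47 ± 0.20 and -0.25 ± 0.15 (adjusted p = 0.324 and 0.495). Irf4, Klf4 and Notch2, which act in cDC2, differed by -0.28 ± 0.13, -0.46 ± 0.23 and 0.16 ± 0.13 (adjusted p = 0.385, 0.407 and 0.623). Zeb2, a repressor that favours cDC2 over cDC1, differed by -0.02 ± 0.14 (adjusted p = 0.967).

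The 8 largest increases among genes that met the naming rule were Cd8a (2.11 ± 0.19), Cd24a (2.05 ± 0.15), Chil5 (1.93 ± 0.22), S100a8 (1.92 ± 0.28), S100a9 (1.88 ± 0.22), Dab2 (1.74 ± 0.26), Cd209d (1.56 ± 0.22) and Xcl1 (1.47 ± 0.14). Their adjusted p ran from 0.000454 for Cd24a to 0.013 for Dab2. S100a8 and S100a9 form calprotectin, Dab2 is an endocytic adaptor, and Xcl1 is the chemokine that binds the cDC1 receptor XCR1. A dimmer probe set of Dab2 gave 0.17 and was not called. Chil5, S100a8, S100a9, Dab2 and Cd209d kept the call in 4 of 6 fits with 1 array left out. S100a8 and S100a9 also stand among the 15 neutrophil markers, of which the other 13 were not called and whose set test gave no call (2 higher and 2 lower adjusted over the list alone, adjusted p = 0.865). The 8 largest decreases were Apol7c (-2.39 ± 0.35), H2-M2 (-2.16 ± 0.13), Lyz1 (-2.05 ± 0.15), Pla2g7 (-1.91 ± 0.16), Tnfsf8 (-1.78 ± 0.15), Il12b (-1.72 ± 0.13), Tnf (-1.63 ± 0.23) and Ccl4 (-1.60 ± 0.16). Their adjusted p ran from 0.000233 for H2-M2 to 0.0105 for Apol7c, and Apol7c and Tnf kept the call in 4 of 6 fits. Chil5 in CD24-CD172a+ cDC2 (3.39) and Apol7c in CD24+CD172a+ cDC2 (3.65) lay below the arrays' 25th percentile (3.72), where background was not examined, so their differences can only be read as lower bounds. S100a8 (4.13 ± 0.68) and Cd209d (3.78 ± 0.42) in CD24-CD172a+ cDC2 lay within 1 SD of it, so theirs may be lower bounds too. Lyz1 is a lysozyme, Pla2g7 hydrolyses platelet-activating factor, Tnfsf8 is the CD30 ligand, and H2-M2 is a class Ib molecule of the major histocompatibility complex (MHC).

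Of 29 cell cycle genes measured, 11 rose in CD24+CD172a+ cDC2, none fell and 18 were not called, with 21 higher when adjusted over the list alone. The list's median was 0.70, and camera called it with the preset correlation (adjusted p = 5.96e-23, and adjusted p = 0.105 with an estimated correlation). Its largest increases were in Ccnb2, a mitotic cyclin (1.10 ± 0.15), Birc5, of the chromosomal passenger complex (1.08 ± 0.17), Bub1, a spindle checkpoint kinase (1.08 ± 0.13), and Kif11, a spindle motor (1.07 ± 0.16). Of 17 plasmacytoid dendritic cell markers, 5 rose, none fell and 12 were not called, with 8 higher when adjusted over the list alone (median 0.35, adjusted p = 1.11e-07, and adjusted p = 0.105 with an estimated correlation). These 5 were the lectin Cd209d, the surface receptor Siglech (1.08 ± 0.14), Tcf4, Atp1b1 (0.88 ± 0.13) and the transcription factor Spib (0.83 ± 0.15). Beside these groups, none of 15 T cell, 14 NK cell or 8 erythroid markers was called, and 1 of 15 B cell markers, Bank1, fell by 0.95 ± 0.16. Siglech kept the call in 5 of 6 fits with 1 array left out, Bub1 and Cd209d in 4, Ccnb2, Birc5, Kif11, Tcf4, Atp1b1 and Bank1 in 3, and Spib in 2. The 2 fits in which Spib kept it drop a cDC1 array, which is not compared here.

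Monocyte and macrophage markers were lower in CD24+CD172a+ cDC2, with 7 of 22 fallen, none risen and 15 not called, and 13 lower when adjusted over the list alone (median -0.42, adjusted p = 6.98e-08, and adjusted p = 0.105 with an estimated correlation). They included Spic, a regulator of red pulp macrophages (-1.56 ± 0.20), Treml4 (-1.23 ± 0.17), Adgre1, a macrophage surface marker (-1.12 ± 0.16), and Lyz2, lysozyme M (-1.09 ± 0.14). The other 3, chosen after their values were seen, were the complement genes C1qa (-0.88), C1qb (-0.93) and C1qc (-0.82). No monocytes or macrophages were arrayed, and whether such cells in the CD24-CD172a+ sort contributed to these values was not tested. Of 26 interferon-stimulated genes, 3 fell, none rose and 23 were not called: Ifit3 (-1.02 ± 0.14), Rtp4 (-0.93 ± 0.13) and Oasl1 (-0.68 ± 0.14). Adjusted over the list alone, 10 were lower and 1 higher (median -0.41, adjusted p = 1.11e-07, and adjusted p = 0.105 with an estimated correlation). Of 23 innate sensors, 2 fell, none rose and 21 were not called, namely Tlr7, a receptor for single-stranded RNA (-1.39 ± 0.21), and Ifih1, a sensor of double-stranded RNA (-1.03 ± 0.15). Adjusted over the list alone, 5 were lower and 1 higher (median -0.24, adjusted p = 0.000296, and adjusted p = 0.253 with an estimated correlation), and fry did not call the list (adjusted p = 0.0695). Of these genes, Spic, Treml4 and Lyz2 kept the call in 4 of 6 fits with 1 array left out, Adgre1, Ifit3, Rtp4, Tlr7 and Ifih1 in 3, and Oasl1 in none.

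Of 27 chemokines and receptors, 4 fell, none rose and 23 were not called, with 10 lower and 1 higher when adjusted over the list alone (median -0.22, adjusted p = 0.0020, and adjusted p = 0.152 with an estimated correlation). The 4 were Ccl4, Ccl2 (-1.41 ± 0.15), the decoy receptor gene Ccrl2 (-1.27 ± 0.27) and Ccl3 (2.01-fold lower). Of 37 cytokines and cytokine receptors, 5 fell, none rose and 32 were not called, with 9 lower and 3 higher when adjusted over the list alone (median -0.13, adjusted p = 0.00211, and adjusted p = 0.349 with an estimated correlation). Il12b, Tnf, Il15 (-1.37 ± 0.28) and Il6 (-0.96 ± 0.18) were among them. The call of this list ended without CD24-CD172a+ replicate 2 (adjusted p = 0.0829), and fry did not call it (adjusted p = 0.0726). Of 26 maturation genes, 5 fell, none rose and 21 were not called, with 8 lower when adjusted over the list alone (median -0.18, adjusted p = 6.08e-06, and adjusted p = 0.349 with an estimated correlation). Il12b and Il15 stand in this list too, beside Socs2, which restrains cytokine signalling and was 2-fold lower, and the tetraspanin Cd63 (-0.71 ± 0.14). A dimmer probe set of Socs2 gave -0.57 and was not called. Il15 in CD24+CD172a+ cDC2 (3.98 ± 0.40) lay within 1 SD of the arrays' 25th percentile (3.72), so its difference may be a lower bound. Fry did not call the maturation list (adjusted p = 0.0726). Ccl2 kept the call in 5 of 6 fits with 1 array left out, Ccl3 in 3, Il15, Il6 and Socs2 in 2, Ccrl2 in 1 and Cd63 in none. The 2 fits in which Il15, Il6 and Socs2 kept it drop a cDC1 array, which is not compared here.

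**Figure D2:**
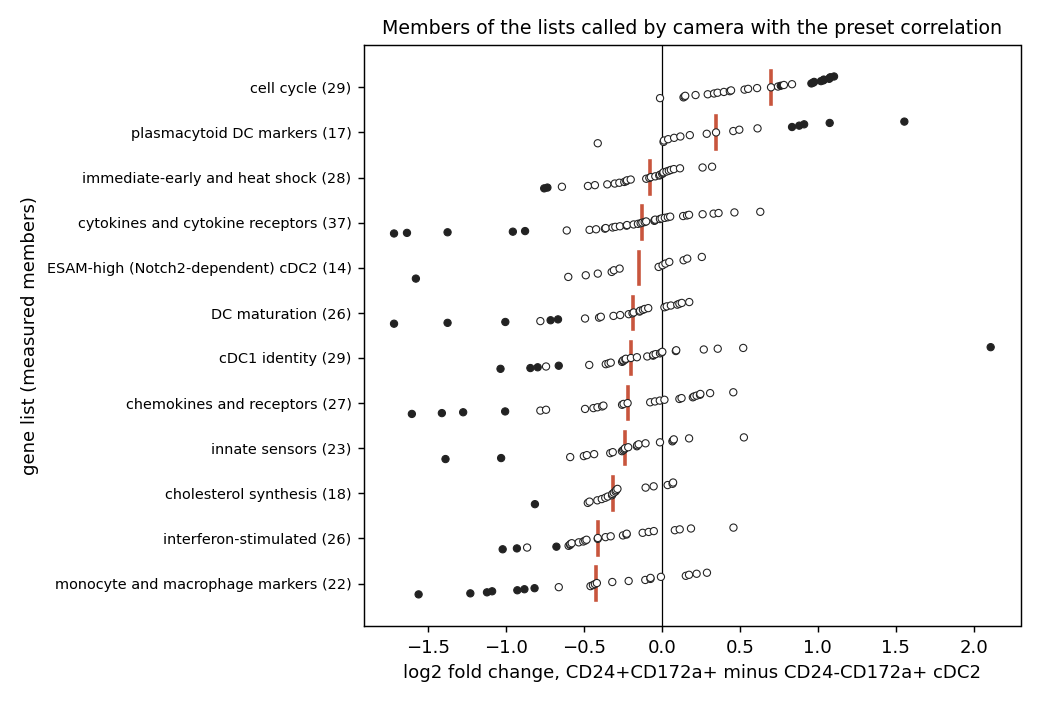
Log2 fold change of CD24+CD172a+ minus CD24-CD172a+ cDC2 (x axis) for each measured member of the 12 gene lists that camera called with the preset correlation (y axis, number of members in brackets); filled dots are called genes, open dots are not, and red bars are list medians. The cell cycle list had the highest median, 0.70, and the monocyte and macrophage markers the lowest, -0.42.

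Of 19938 genes tested, 291 were called between the cDC2 populations, 161 higher and 130 lower in CD24+CD172a+ cDC2, of which 33 and 48 changed by at least 2-fold. Against a 1.5-fold change, limma's treat called 8. Cyclic loess normalisation gave 126 higher and 160 lower, so the larger direction depends on the scaling. Leaving out 1 array gave 20 calls without CD24+CD172a+ replicate 1, 44 without CD24+CD172a+ replicate 2, 98 and 76 without CD24-CD172a+ replicates 1 and 2, and 187 without either cDC1 replicate. Of 57 named genes called here, 10 kept the call in each of these 6 fits: Cd24a, Cd8a, Xcl1, H2-M2, Lyz1, Pla2g7, Tnfsf8, Il12b, Ccl4 and Cd81. Another 6 kept it in none: Id2, Oasl1, Cd63, Atf3, Cadm1 and Ly75.

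**Figure D3:**
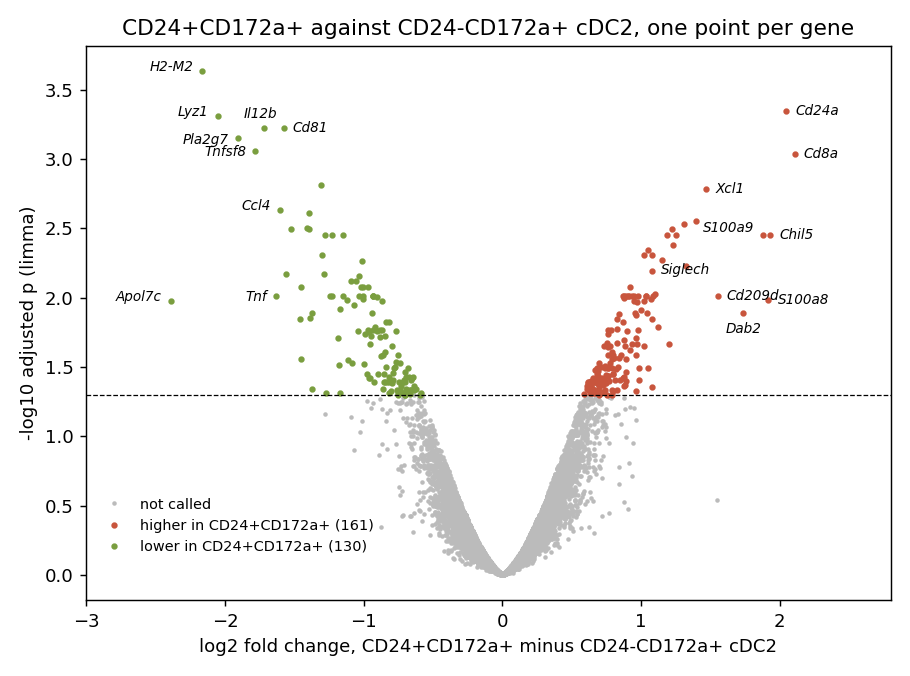
Log2 fold change (x axis) against -log10 adjusted p from limma (y axis) for CD24+CD172a+ against CD24-CD172a+ cDC2, with 1 point per gene; red and green points are the 161 higher and 130 lower genes and the dashed line is an adjusted p of 0.05. Cd24a and Cd8a lie at 2.05 and 2.11, and H2-M2, with the smallest adjusted p, at -2.16.

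The second comparison sets CD24+CD172a+ cDC2 against cDC1, with which they share CD24. Cd24a was 1.83-fold lower in CD24+CD172a+ cDC2 (10.88 ± 0.09 against 11.74 ± 0.12, SD, n = 2), and Sirpa was 31.1-fold higher (10.14 ± 0.18 against 5.18 ± 0.29). Xcr1, the receptor for XCL1 that marks cDC1, was 48.2-fold lower, at 5.12 ± 0.47 against 10.71 ± 0.00. Cybb, the catalytic subunit of the phagocyte oxidase, was 43.1-fold higher, at 9.73 ± 0.28 against 4.30 ± 0.04.

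Irf8 fell by 2.79 ± 0.20 (adjusted p = 4.2e-06), Id2 by 1.31 ± 0.14 (adjusted p = 7.53e-05) and Batf3 by 0.52 ± 0.15 (adjusted p = 0.0397). The call of Batf3 ended without cDC1 replicate 1 (adjusted p = 0.275) or without CD24+CD172a+ replicate 1 or 2 (adjusted p = 0.236 and 0.0825). Irf4 rose by 2.28 ± 0.13 (adjusted p = 1.11e-06), Zeb2 by 3.97 ± 0.14 (adjusted p = 3.23e-08) and Tcf4 by 1.76 ± 0.13 (adjusted p = 5.23e-06). Notch2 differed by 0.04 ± 0.13 (adjusted p = 0.915). Klf4 differed by 0.71 ± 0.23 (adjusted p = 0.0759). Its difference was 0.41 without cDC1 replicate 1 and 0.39 without CD24+CD172a+ replicate 2 (adjusted p = 0.446 and 0.460), while it was called without cDC1 replicate 2 (adjusted p = 0.0341), without CD24+CD172a+ replicate 1 (adjusted p = 0.0350), with the replicate number as a block (adjusted p = 0.00627) and without genes below the median (adjusted p = 0.0471). After Cybb, the largest increases were in the lectin Clec4a1 (5.25 ± 0.13), S100a4 (5.13 ± 0.13), Cd7 (5.06 ± 0.15), Sirpa (4.96 ± 0.16), the lectin Clec4a4 (4.85 ± 0.16), Ms4a4c (4.77 ± 0.17) and Klrd1, which encodes CD94 (4.74 ± 0.14). The largest decreases were in Gpr141b (-6.70 ± 0.25), Ifi205 (-6.43 ± 0.15), P3h2 (-6.14 ± 0.13), the scavenger receptor gene Cd36 (-5.64 ± 0.13), Xcr1 (-5.59 ± 0.21), the nucleotide-sugar receptor gene P2ry14 (-5.55 ± 0.17), Cadm1 (-4.81 ± 0.17) and Apol7c (-4.60 ± 0.35). Clec4a1 (2.79) and Clec4a4 (3.21) in cDC1, and P3h2 (3.34) and Apol7c (3.65) in CD24+CD172a+ cDC2, lay below the arrays' 25th percentile (3.72), so their differences can only be read as lower bounds, without a rank.

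Of 29 cDC1 identity genes, 27 fell in CD24+CD172a+ cDC2, none rose and 2 were not called, with 28 lower when adjusted over the list alone (median -2.73, adjusted p = 4.77e-39, and adjusted p = 0.0904 with an estimated correlation). Of 29 cDC2 identity genes, 23 rose, 3 fell and 3 were not called, with 24 higher and 3 lower when adjusted over the list alone (median 1.77, adjusted p = 2.78e-25, and adjusted p = 0.0904 with an estimated correlation). Of 26 interferon-stimulated genes, 14 rose and 3 fell, counts that were the same adjusted over the list alone, and Rtp4 (3.56 ± 0.13) rose by the most (median 0.62, adjusted p = 7.67e-07, and adjusted p = 0.128 with an estimated correlation). Of 23 innate sensors, 10 rose and 4 fell, with 12 and 5 adjusted over the list alone (median 0.43, adjusted p = 0.000599, and adjusted p = 0.221 with an estimated correlation). Tlr3 fell by 4.24 ± 0.13 and Tlr7, at 3.01 in cDC1 and so a lower bound too, rose by 4.05 ± 0.21. Of 20 genes of MHC class I presentation, 14 fell and 1 rose, with 15 and 1 adjusted over the list alone (median -0.72, adjusted p = 3.19e-07, and adjusted p = 0.20 with an estimated correlation). Tapbpl, a peptide editor (-1.54 ± 0.14), fell by the most, and the gene that rose was Cybb.

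The cell cycle list was also higher than in cDC1, with 13 of 29 genes risen, none fallen and 15 higher when adjusted over the list alone (median 0.49, adjusted p = 8.05e-07, and adjusted p = 0.221 with an estimated correlation). Bub1 rose by 1.26 ± 0.13 and Top2a, which untangles DNA, by 1.05 ± 0.14. A dimmer probe set of Top2a gave 0.87 and was called, but it gave -0.18 against CD24-CD172a+ cDC2 and was not called there. Of 17 plasmacytoid markers, 6 rose and 2 fell, with 8 and 3 adjusted over the list alone (median 0.30, adjusted p = 0.00239, and adjusted p = 0.168 with an estimated correlation). Spib rose by 2.12 ± 0.15, and the chemokine receptor gene Ccr9 fell by 1.79 ± 0.16. Of 15 neutrophil markers, 4 rose and none fell, with 5 higher when adjusted over the list alone (median 0.13, adjusted p = 0.0218, and adjusted p = 0.221 with an estimated correlation). These were S100a9 (1.52 ± 0.22), S100a8 (1.23 ± 0.28), Mmp9 (0.84 ± 0.20) and Csf3r (0.71 ± 0.13). The call of the neutrophil list ended without CD24+CD172a+ replicate 1 (adjusted p = 0.102). That of S100a8 ended without cDC1 replicate 1 or 2 or CD24+CD172a+ replicate 1 (adjusted p = 0.0854, 0.0512 and 0.148), and that of Mmp9 without cDC1 replicate 1, where its difference was 0.53, or CD24+CD172a+ replicate 1 or 2 (adjusted p = 0.137, 0.0504 and 0.141).

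In total 2718 genes were called between CD24+CD172a+ cDC2 and cDC1, 1418 higher and 1300 lower, of which 477 and 450 changed by at least 2-fold. Leaving out cDC1 replicate 1 gave 1805 calls, and leaving out CD24+CD172a+ replicate 1 or 2 gave 1781 or 1810. Against a 1.5-fold change, limma's treat called 715. Of 92 named genes called here, 84 kept the call in each of the 6 fits with 1 array left out, and none lost it in all of them.

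The third comparison sets CD24-CD172a+ cDC2 against cDC1, a contrast of both surface markers. Cd24a was 7.55-fold lower in CD24-CD172a+ cDC2 (8.83 ± 0.20 against 11.74 ± 0.12, SD, n = 2), and Sirpa was 32.2-fold higher (10.19 ± 0.01 against 5.18 ± 0.29). Mmp12, the macrophage elastase, was 66.5-fold higher, at 10.27 ± 0.12 against 4.22 ± 0.41. Cd8a was 46.1-fold lower (5.47 ± 0.22 in CD24-CD172a+ cDC2).

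Irf8 fell by 2.33 ± 0.20 (adjusted p = 1.65e-05) and Id2 by 0.64 ± 0.14 (adjusted p = 0.00818), while Irf4 rose by 2.56 ± 0.13 (adjusted p = 4.53e-07), Zeb2 by 3.99 ± 0.14 (adjusted p = 2.95e-08), Klf4 by 1.17 ± 0.23 (adjusted p = 0.00575) and Tcf4 by 0.85 ± 0.13 (adjusted p = 0.00103). The call of Klf4 ended without cDC1 replicate 1 (adjusted p = 0.0590), and that of Id2 without cDC1 replicate 2 or CD24-CD172a+ replicate 1 (adjusted p = 0.0580 and 0.0602). Batf3 and Notch2 differed by -0.27 ± 0.15 and -0.13 ± 0.13 (adjusted p = 0.283 and 0.619). After Mmp12, the largest increases were in Clec4a1 (5.81 ± 0.13), Tlr7 (5.44 ± 0.21), Clec4a4 (5.34 ± 0.16), Cybb (5.23 ± 0.15), S100a4 (5.09 ± 0.13), Sirpa (5.01 ± 0.16) and Adgre1 (4.72 ± 0.16). The largest decreases were in Gpr141b (-6.80 ± 0.25), Ifi205 (-6.77 ± 0.15), P3h2 (-5.68 ± 0.13), P2ry14 (-5.68 ± 0.17), Cd8a (-5.53 ± 0.19), the acid amidase gene Naaa (-5.05 ± 0.15), Xcr1 (-4.85 ± 0.21) and Cd36 (-4.60 ± 0.13). In cDC1, Clec4a1 (2.79), Tlr7 (3.01) and Clec4a4 (3.21) lay below the arrays' 25th percentile (3.72), so their differences can only be read as lower bounds, without a rank.

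Of 29 cDC1 identity genes, 26 fell and none rose, with 27 lower when adjusted over the list alone (median -2.29, adjusted p = 5.16e-34, and adjusted p = 0.0811 with an estimated correlation). Of 29 cDC2 identity genes, 24 rose and 2 fell, with 25 and 3 adjusted over the list alone (median 1.91, adjusted p = 9.22e-25, and adjusted p = 0.0811 with an estimated correlation). Of 26 interferon-stimulated genes, 16 rose and 3 fell, with 19 and 3 adjusted over the list alone, Rtp4 by 4.49 ± 0.13 and Ifit3 by 3.19 ± 0.14 (median 0.92, adjusted p = 1.03e-10, and adjusted p = 0.0811 with an estimated correlation). Of 23 innate sensors, 14 rose and 3 fell, with 17 and 3 adjusted over the list alone (median 0.77, adjusted p = 1.08e-06, and adjusted p = 0.139 with an estimated correlation). Tlr1 rose by 3.41 ± 0.13, and Tlr3 fell by 4.23 ± 0.13. Of 22 monocyte and macrophage markers, 9 rose and 3 fell, with 10 and 3 adjusted over the list alone (median 0.39, adjusted p = 0.00236, and adjusted p = 0.139 with an estimated correlation). Besides Adgre1, Csf1r, the receptor for macrophage colony-stimulating factor, rose by 3.59 ± 0.14 and Ace by 2.08 ± 0.21, while Treml4 fell by 2.30 ± 0.17. The cell cycle list was lower than in cDC1, with 5 of 29 genes fallen and none risen, counts that were the same adjusted over the list alone (median -0.25, adjusted p = 0.0177, and adjusted p = 0.458 with an estimated correlation). Mcm6, of the replicative helicase, fell by 1.04 ± 0.14 and Rrm2, of ribonucleotide reductase, by 0.79 ± 0.16, a call that ended without cDC1 replicate 1 (adjusted p = 0.0650). The call of the cell cycle list ended without CD24-CD172a+ replicate 1 (adjusted p = 0.0942), with cyclic loess normalisation (adjusted p = 0.0556) and without genes below the median (adjusted p = 0.111), and fry did not call the list (adjusted p = 0.0903).

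In total 3137 genes were called between CD24-CD172a+ cDC2 and cDC1, 1361 higher and 1776 lower, of which 492 and 466 changed by at least 2-fold. Cyclic loess normalisation gave 1560 higher and 1472 lower, so here too the larger direction depends on the scaling. Leaving out cDC1 replicate 1 gave 1922 calls, and limma's treat against a 1.5-fold change called 728. Of 92 named genes called here, 79 kept the call in each of the 6 fits with 1 array left out, and 2, Mmp8 and Nkg7, kept it in none.

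Genes that set CD24+CD172a+ cDC2 apart from both other populations were counted next. Dab2, Cd209d, S100a9, Xcl1, S100a8 and Klra17, a killer-lectin family gene, stood the farthest above both. Xcl1 had 8.91 ± 0.02 in CD24+CD172a+ cDC2 and 7.44 ± 0.04 in CD24-CD172a+ cDC2 (SD, n = 2), and rose by 2.65 against cDC1. Klra17 rose by 1.22 against CD24-CD172a+ cDC2 and by 4.28 against cDC1. Apol7c, Il12b, Lyz1, the tetraspanin gene Cd81, AW112010 and the chemokine gene Ccl2 stood the farthest below both. Apol7c in CD24+CD172a+ cDC2 (3.65) and Cd209d in cDC1 (3.66) lay below the arrays' 25th percentile (3.72). Both differences of Apol7c, and that of Cd209d against cDC1, can thus only be read as lower bounds. In CD24-CD172a+ cDC2, Cd209d (3.78 ± 0.42) and S100a8 (4.13 ± 0.68) lay within 1 SD of that percentile. Their differences from that population may be lower bounds too. Klra17 and AW112010 lost the call against CD24-CD172a+ cDC2 in some fits with 1 array left out. Il12b fell by 1.72 against CD24-CD172a+ cDC2 and by 3.69 against cDC1, while Cd81 fell by 1.58 against the former and fell by 3.50 against the latter.

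In all, 81 genes were higher in CD24+CD172a+ cDC2 than in both others, and 61 were lower. Independent lists of the same sizes would share 11.5 and 8.48 genes, and 100 simulations of unchanged groups gave means of 0.01 and 0.03. No gene differed in those simulations, so they could give almost no overlap and are no measure for lists of these sizes. The comparisons share the 2 CD24+CD172a+ arrays, and a split would leave 1 array to each, so part of the excess may come from that sharing. The covariance of their fold changes was 0.0250, against 0.0116 in the simulations (r = 0.194 against 0.50). Without cDC1 replicate 1 or 2 the 81 became 50 or 48, without CD24+CD172a+ replicate 1 or 2 they became 7 or 11, and without CD24-CD172a+ replicate 1 or 2 they became 31 or 36. The 61 became 35 or 34, 5 or 15, and 24 or 16 in the same order. Over all probe sets, 36 were higher and 19 lower than in both others, and treat against a 1.5-fold change gave 0 and 3. Of the 161 genes that rose against CD24-CD172a+ cDC2, 14 were lower than in cDC1, Cd8a and Cd24a among them, and 66 were not called against cDC1.

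The cDC2 populations shared most of their distance from cDC1. Among the called genes, 982 were higher and 1043 lower than in cDC1 in both, Sirpa, Zeb2 and Irf4 among the higher and Xcr1, Irf8 and Cd36 among the lower. Independent lists would share 96.8 and 115.8, and the simulations gave 0.03 and 0.01, with the cDC1 arrays in common. Here too the simulations could give almost no overlap, since no gene differed in them. The covariance of the fold changes was 0.238, against 0.0116 in the simulations (r = 0.884 against 0.50).

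The level of CD24+CD172a+ cDC2 was also placed on a scale from 0, at CD24-CD172a+ cDC2, to 1, at cDC1. Over 200 genes with the largest difference between those populations, chosen on one pair of arrays and measured on the other, the median position was 0.0451, with quartiles of -0.0439 and 0.154. Genes higher in cDC1 lay at 0.0130 and genes higher in cDC2 at 0.0634. The SD over the 2 CD24+CD172a+ arrays was 0.00529, and the SD over the arrays used to choose the genes was 0.00993. The position was 0.0247 over 50 genes, -0.00228 over members of the cDC1 and cDC2 identity lists, and 0.161 over the called genes chosen and measured on the same arrays.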

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

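All alternatives here were planned before the data were examined. With 2 arrays per group and no detection calls, signal over background could not be set against these values, and a group left with 1 array is assumed to vary like the others. The cause of each difference was not tested, except that a fold threshold lowers a count by construction.

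For CD24+CD172a+ against CD24-CD172a+ cDC2, the 291 calls became 437 without genes below the median, 102 over all probe sets, 464 with an intensity trend and robust variance, 187 with only the 2 groups compared, and 8 with treat. Treat also gave 715 and 728 calls for CD24+CD172a+ and CD24-CD172a+ cDC2 against cDC1. Genes higher in CD24+CD172a+ cDC2 than in both others numbered 36 over all probe sets and 0 with treat (30 at an unadjusted p under 0.05). Genes lower than in both numbered 19 over all probe sets, 40 with only 2 groups compared and 3 with treat. The position became 0.0589 with cyclic loess, 0.0247 over 50 genes, -0.00228 over the identity lists and 0.161 over genes called on the same arrays. Camera with an estimated correlation called 0 lists in each comparison (6, 6 and 7 at an unadjusted p under 0.05), against 12, 13 and 15 with the preset one, and fry called 6, 20 and 17. With 1 array left out, calls ranged from 20 to 187, from 1781 to 2769 and from 1922 to 2839 in the 3 comparisons, genes higher than in both others from 7 to 50, and genes lower than in both from 5 to 35. The upper ends of the ranges of calls in the 3 comparisons come from fits that drop an array of the population not compared. They equal the counts with only the 2 groups compared, and each fit that drops a compared array lay below them. With 1 array left out, uncalled Sirpa between the cDC2 populations ranged from -0.177 to 0.0769, and uncalled Notch2 in CD24+CD172a+ cDC2 against cDC1 from -0.0424 to 0.114.

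The other counts stayed within 1.5 times. Over all settings, the tests of named genes kept their side of the threshold and direction in 4327 cases, lost the call in 369, gained it in 5 and, uncalled, changed sign in 2, those of called lists kept it in 412 and lost it in 66, and of 479 tests of uncalled lists 24 gave a call and 42 another sign. No label says whether equal replicate numbers share anything. The differences between replicates correlated across genes at 0.0837, 0.0242 and 0.0838 between groups, low values that cannot exclude pairing. The replicate block gave 411, 2918 and 3323 calls, against 291, 2718 and 3137 without it, and kept all 12, 13 and 15 lists. Whether the arrays are paired stays open.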

Other observations

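All tests of explanations in this part were chosen after the result was seen. Other gene groups also differed between the cDC2 populations. In CD24+CD172a+ cDC2, 1 of 18 cholesterol synthesis genes fell, the squalene synthase gene Fdft1 (-0.81 ± 0.13, and -0.73 by a dimmer probe set that was not called), with 5 lower when adjusted over the list alone (median -0.31, adjusted p = 7.55e-06, and adjusted p = 0.105 with an estimated correlation). Of 29 cDC1 identity genes, Cd8a rose and 4 fell, among them Cd36 (-1.03 ± 0.13), Cadm1 (-0.84 ± 0.17) and the endocytic receptor gene Ly75 (-0.80 ± 0.16), with 2 higher and 5 lower when adjusted over the list alone (median -0.20, adjusted p = 0.01249, and adjusted p = 0.461 with an estimated correlation). Of 14 genes of ESAM-high cDC2, Cd81 fell (-1.58 ± 0.13), with 4 lower when adjusted over the list alone (median -0.15, adjusted p = 0.01249, and adjusted p = 0.329 with an estimated correlation). Of 28 immediate-early and heat shock genes, Ier3 (-0.75 ± 0.13) and Atf3 (-0.73 ± 0.15) fell, with 3 lower when adjusted over the list alone (median -0.08, adjusted p = 0.01368, and adjusted p = 0.669 with an estimated correlation). Without CD24+CD172a+ replicate 1 the cDC1 identity, ESAM-high and immediate-early lists were not called (adjusted p = 0.184, 0.149 and 0.768), nor were they without CD24-CD172a+ replicate 2 (adjusted p = 0.146, 0.0891 and 0.368), and fry, which compares a list with no other genes, did not call them either (adjusted p = 0.209, 0.0642 and 0.392). The other 15 lists were not called by camera. Among their genes, the class II gene H2-Eb2 fell by 0.93 ± 0.13, the only called one of 16 in MHC class II presentation, also adjusted over the list alone (adjusted p = 0.644 for the list). Nlrc5, which activates class I genes, fell by 0.86 ± 0.15, the only called one of 20 in MHC class I presentation, also adjusted over the list alone (adjusted p = 0.848). Of 19 probe sets of Nlrc5, 3 were called, and the second brightest gave -0.01 (adjusted p = 0.993). Among 27 C-type lectins, Cd209d rose and Clec4n (-1.29 ± 0.16) and Ly75 fell, with 4 higher and 6 lower when adjusted over the list alone (adjusted p = 0.194). Among 27 integrins and adhesion molecules, Cd24a and Itgb3 (0.79 ± 0.16) rose and Itgav (-0.87 ± 0.14) and Cadm1 fell, with 2 and 4 adjusted over the list alone (adjusted p = 0.278). Tcf4 and Spib rose and Id2 fell among 30 transcription factors, counts that were the same adjusted over the list alone (adjusted p = 0.936, where the median of -0.04 was below 0 and the test above). Lyz1 and Lyz2 fell among 18 genes of ESAM-low cDC2, with 3 lower and 1 higher when adjusted over the list alone (adjusted p = 0.343, with a median of 0.02 and a mean of -0.16). Tlr7 and Lyz2 fell among 29 cDC2 identity genes, with 7 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0921). The cDC2 identity list was called without genes below the median (adjusted p = 0.00130), with cyclic loess (adjusted p = 0.00269), without CD24+CD172a+ replicate 2 (adjusted p = 0.0449) and without CD24-CD172a+ replicate 1 (adjusted p = 0.0265). Without genes below the median the C-type lectin, ESAM-low and Notch lists were called too (adjusted p = 0.000680, 0.0214 and 0.0429), and the lectins were also called without CD24-CD172a+ replicate 1 (adjusted p = 0.0324). Siglech and Tcf4 rose and Cd81, Socs2 and Nudt17 (-0.99 ± 0.16) fell among 16 markers of migratory and transitional dendritic cells, with 3 and 4 adjusted over the list alone (adjusted p = 0.848, with a median of 0.07 and a mean of -0.07). None of 23 Notch pathway genes or 10 granule and cytotoxic genes was called, also adjusted over the list alone (adjusted p = 0.278 and 0.112), with the smallest p in Hey1 (-0.53 ± 0.15) and Gzmb (-0.42 ± 0.14). The B, T, NK and erythroid marker lists gave an adjusted p of 0.644, 0.963, 0.207 and 0.848, with 2 B cell markers lower when adjusted over the list alone. With 1 array left out, Cd36 kept the call in 5 of 6 fits, H2-Eb2, Clec4n and Itgav in 3, Fdft1, Ier3, Nlrc5 and Nudt17 in 2, Itgb3 in 1, and Cadm1, Ly75 and Atf3 in none. The 2 fits in which Fdft1, Ier3, Nlrc5 and Nudt17 kept it drop a cDC1 array, which is not compared here.

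Against cDC1, both cDC2 populations were higher in further groups. Of 18 genes of ESAM-low cDC2, 12 rose and 3 fell in CD24+CD172a+ cDC2, with 13 and 3 adjusted over the list alone (adjusted p = 1.61e-07, and adjusted p = 0.128 with an estimated correlation), and 12 rose and 1 fell in CD24-CD172a+ cDC2, with 14 and 1 adjusted over the list alone (adjusted p = 8.46e-11, and adjusted p = 0.0811 with an estimated correlation). Cd209a, a lectin of the DC-SIGN family, rose by 4.12 ± 0.12 and 4.09 ± 0.12. Of 14 genes of ESAM-high cDC2, 5 and 6 rose and 1 fell in each, with 6 and 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.00733 and 0.000936, and adjusted p = 0.221 and 0.168 with an estimated correlation). Cd4 rose by 2.30 ± 0.13 and 2.71 ± 0.13. Of 27 C-type lectins, 16 rose and 6 fell in each, with 17 and 16 higher and 6 lower adjusted over the list alone (adjusted p = 8.05e-07 and 1.81e-06, and adjusted p = 0.128 and 0.115 with an estimated correlation), Klrd1 by 4.74 ± 0.14 and 4.45 ± 0.14, while Clec9a fell by 4.45 ± 0.13 and 4.40 ± 0.13. Of 30 transcription factors, 9 and 11 rose and 5 and 4 fell, with 12 higher in each and 6 and 5 lower adjusted over the list alone (adjusted p = 0.000599 and 0.00221, and adjusted p = 0.335 and 0.374 with an estimated correlation). Of 37 cytokines and receptors, 13 and 14 rose and 4 and 3 fell, with 15 and 17 higher and 7 and 4 lower adjusted over the list alone (adjusted p = 0.0218 and 0.000558, and adjusted p = 0.409 and 0.260 with an estimated correlation). Csf1r and Il21r rose by 3.77 ± 0.14 and 2.68 ± 0.13 in CD24+CD172a+ cDC2, where the call of the list ended without CD24+CD172a+ replicate 2 (adjusted p = 0.0839) and without genes below the median (adjusted p = 0.144). In CD24-CD172a+ cDC2, 13 of 20 genes of MHC class I presentation fell and 1 rose, also adjusted over the list alone (adjusted p = 5.81e-07, and adjusted p = 0.168 with an estimated correlation). Camera there also called the maturation list, with 9 risen and 3 fallen of 26 and 13 and 4 adjusted over the list alone, the immediate-early list, with 6 and 2 of 28 and 8 and 3, and NK cell markers, with 3 and 0 of 14 in both counts (adjusted p = 0.0119, 0.0166 and 0.0177, and adjusted p = 0.458, 0.545 and 0.192 with an estimated correlation). Cd274, which encodes PD-L1 (1.95 ± 0.14), Jun (1.42 ± 0.14) and Klri2 (3.67 ± 0.16) were among their increases. Without cDC1 replicate 1 the maturation and immediate-early lists were not called (adjusted p = 0.111 for both), nor did fry call them (adjusted p = 0.0829 and 0.171), nor was the latter without CD24-CD172a+ replicate 2 (adjusted p = 0.154) or the NK list without cDC1 replicate 2 (adjusted p = 0.0519).

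The 4.31-fold higher Cd8a of CD24+CD172a+ over CD24-CD172a+ cDC2 could come from cDC1 or T cells carried over into that sort, although the CD172a gate is set against both. A share of 7.35% of cDC1 signal would give the Cd8a difference, but over the 30 genes with the largest excess in cDC1 the observed change minus the one that share predicts had a median of -1.22 (0.02 observed, 1.11 predicted) and was negative in all 30, which argues against cDC1. Xcr1, abundant in cDC1, had 5.12 ± 0.47 in CD24+CD172a+ and 5.86 ± 0.30 in CD24-CD172a+ cDC2. The 90th percentile of the changes of 15 T cell markers was 0.0548, so as a group they did not rise with Cd8a. Of the 15, 4 lay above the median gene in CD24-CD172a+ cDC2 and 1 is held by another list. No T cells were arrayed, so the rise that a share of them would cause is not known, and T cells are not excluded. The markers did not all go down: Lat had 5.12 ± 0.27 against 4.80 ± 0.22 and Cd3d 4.12 ± 0.02 against 4.51 ± 0.05, neither of them called. Other sources of Cd8a, among them the plasmacytoid dendritic cells considered below, were not tested. That cDC2 with surface CD24 express more Cd8a stays open as an untested hypothesis.

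The higher cell cycle list of CD24+CD172a+ cDC2 could reflect a mixture of the other populations, a single array, or cycling cells of another lineage. CD24+CD172a+ cDC2 exceeded the higher of the other means in 22 of 29 genes, of which 8 were called above both other populations. For Top2a, 1 of the 8, a dimmer probe set gave -0.18 against CD24-CD172a+ cDC2 and was not called. The lower quartile of the excess was 0.12, below the median standard error of a difference over all genes (0.143). The excess argues against a mixture of those populations, most directly for the 8 called genes. The lowest median with 1 array left out was 0.619, which argues against a single array. Markers of B, T, NK, neutrophil and erythroid cells had a median change of 0.00475, with 35 of 67 higher, S100a8 (1.92 ± 0.28) and S100a9 (1.88 ± 0.22) among them. Plasmacytoid markers, outside that set, were higher in 16 of 17, with a median of 0.35 and 5 called. The markers of the first set went both ways and no cycling cells of any of these lineages were arrayed, so this source cannot be told apart from cycling within the population. A larger share of cycling cells among CD24+CD172a+ cDC2 stays open as an untested hypothesis.

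The higher plasmacytoid list could come from plasmacytoid dendritic cells in the CD24+CD172a+ sort, and the labels do not say whether a gate removed them. Of its 17 genes, 29.4% were called higher and 16 had a higher mean, with Siglech at 5.86 ± 0.18 against 4.78 ± 0.06 and Tcf4 at 7.77 ± 0.08 against 6.86 ± 0.10. Of the 17, CD24-CD172a+ cDC2 also expressed 7 above the median gene, and 6 stand in another list. No plasmacytoid dendritic cells were arrayed, so carry-over cannot be told apart from expression of these genes by CD24+CD172a+ cDC2. The latter stays open as an untested hypothesis.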
